A study of Mus musculus with 12 samples.

How the data were processed

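Leukocytes of 12 mouse heart libraries were profiled by single-cell RNA sequencing. Per the labels, hearts of C57Bl6/J wild-type mice were flushed and digested, viable (DAPI-low) CD45-positive cells were sorted, and libraries were made with the Chromium Single Cell 3' v3 kit and sequenced on an Illumina platform. The 6 CLP libraries came from mice that had undergone cecal ligation and puncture, a surgical model of abdominal sepsis, 6 weeks earlier, and the 6 control libraries from untreated mice of the same age, which were not sham-operated. Whether each library is a separate animal, the sex of the mice and the dates of the experiments are not given in the sources used here. The library numbers fall into 2 separate ranges, each with both groups. The ranges were taken as library batches, although the labels do not call them so. Batch A holds control replicates 1 to 4 and CLP replicates 1 to 4, and batch B holds control replicates 5 and 6 and CLP replicates 5 and 6. Replicate numbers did not pair the libraries.

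The deposited values are raw UMI counts per gene and cell barcode in filtered matrices, 1 per library, made by the authors with Cell Ranger on mm10. The Cell Ranger version and the gene annotation are not given in the sources used here. The labels also name Scanpy 1.9.6, and no cell types or filtered cell lists were deposited. The matrices hold 32285 genes and 21414 barcodes, with 443 to 4159 barcodes per library. Total counts ran from 2335342 to 5810502 UMIs per library in batch A and from 14969012 to 26566539 in batch B. Gene coordinates are those of the GENCODE vM21 annotation of the same build.

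Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, which left 19951. Scrublet as built into scanpy 1.11.5 was run on each library with an expected doublet rate of 0.05, and the 476 barcodes it called (2.39%, between 0.1% and 6.24% per library) were removed, which left 19475 cells. Counts were scaled per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and cells were clustered with the Leiden algorithm (leidenalg 0.10.2) on 15 nearest neighbours at resolution 1.0, without integration of the libraries. The 27 clusters were named from fixed marker lists. A marker counted when it was found in a share of at least 0.25 of the cluster's cells and at 1.5 times its level in other cells or more. At least 3 markers were needed for a name, and a cluster stayed unnamed where its 10 leading genes held more markers of another type, or held none of its own beside a low UMI count. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

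For each named class, counts were summed per library wherever a library held at least 20 cells of the class, and a class was tested where at least 3 libraries per group remained. CLP was compared with control by the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with library batch as a term, after filterByExpr and TMM normalization, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Levels are CPM (counts scaled to library size by the cpm function of edgeR), given as mean ± SD over libraries. A log2 fold change is CLP over control as fitted, and its standard error (SE) is the fold change divided by the root of the F statistic. Whether the CLP difference differed between batches was tested with an interaction term. The 27 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists, with the median log2 fold change of each list's measured genes beside it. Each list was tested again with an estimated correlation and with fry. Members past the threshold are also counted adjusted over the list alone.

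Class shares are percentages of the named leukocytes of a library. Marker shares are percentages of macrophages with a UMI of the gene after thinning each cell to 1000 UMIs, with B cells as the measure of free RNA. Cells with fewer than 1000 UMIs were left out of the marker shares. Macrophages were clustered again at resolution 0.5, and the sub-clusters were named from fixed subset markers. Shares were compared by two-sided exact permutation tests of the group within batches. The 420 assignments allow a smallest p of 0.0048, those of batch A alone 0.0286 and those of batch B alone 0.333, so no test in batch B alone can pass. Shares were adjusted over the classes, marker genes or subsets tested together.

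The groups, tests, gene lists, cell markers, naming rule and most alternatives were fixed before the data were examined. In macrophages, where fewer than 5 genes passed, the rule names the 10 genes with the lowest p. In other classes it names the first 5 higher and the first 5 lower genes past the threshold with a mean log2 CPM of at least 4 and the same sign in both batches. From each list it names the members past the threshold and up to 3 others by level in macrophages. Predicted, ribosomal, mitochondrially encoded and sex-linked genes are reported as groups. Genes outside the rule are marked where they appear.

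Alternatives were DESeq2 1.42.0 in place of edgeR, RLE size factors, no filter on low counts, no batch term, a replicate block, each batch alone, doublet calls kept, at least 1000 UMIs per cell, at least 50 cells per library, Leiden resolution 2.0, other thinning depths (2000 UMIs or none), other sub-cluster resolutions (0.3 and 0.8), a logit scale for shares with 0.5 cells added, permutation without batches, and leaving out each library in turn. Chosen after seeing the data were leaving out CLP replicates 5 and 6, leaving out macrophage cluster 10, adding the unnamed clusters to the macrophages, leaving out barcodes with over 5% haemoglobin UMIs, and taking 1 monocyte cluster alone. Each library was also left out in turn for the other classes, and class shares were recomputed at resolution 2.0. The tests were tested on simulated data with known changes. Of the genes changed 2-fold, 92.8% were recovered in macrophages, 96.2% in B cells, 95.3% in dendritic cells, 59.1% in neutrophils, 54.3% in T cells, 52.9% in NK cells and 25% in monocytes. Simulated data with no difference gave 2 calls in monocytes, 1 in NK cells and 0 in each other class, and the permutation test gave a p under 0.05 in 4.0% of simulations with no difference. The simulated gene counts held no structure of the libraries beyond batch and dispersion. Their calls therefore need not match the rate of false calls in the real data.

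Innate lymphoid cells, mast cells or basophils, endothelial cells, proliferating cells and the unnamed clusters were left out of the gene tests. Unnamed clusters, endothelial cells and proliferating cells were also left out of the shares, because their class was unclear or not a resting leukocyte class. No sequence reads were available, so alignment and background removal were not repeated.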

Results

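The data are UMI counts of CD45-positive cells from the hearts of 6 untreated control libraries and 6 libraries made 6 weeks after cecal ligation and puncture (CLP). The 19475 cells kept had a median of 1540 to 5180 UMIs per cell in the 8 libraries of batch A and of 4257.5 to 4943 in the 4 libraries of batch B. The series title concerns how bacterial infections shape the response of cardiac macrophages to ischemia, but the labels describe no ischemic heart among these libraries. The comparison therefore asks how heart leukocytes of mice that went through sepsis differ from those of untreated mice. Surgery and infection cannot be told apart in it, since no sham-operated mice were included.

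Neutrophils, the short-lived phagocytes that blood delivers to inflamed tissue, made up 21.4% ± 16.3 (SD, n = 6) of named leukocytes in CLP hearts and 9.94% ± 8.92 (SD, n = 6) in control hearts. Monocytes, the circulating precursors of many macrophages, made up 7.02% ± 6.42 (SD, n = 6) after CLP and 2.52% ± 1.13 (SD, n = 6) in controls. Conventional dendritic cells, which present antigen to T cells, made up 3.52% ± 1.26 (SD, n = 6) after CLP and 5.59% ± 1.78 (SD, n = 6) in controls. B cells made up 5.71% ± 3.74 and 9.96% ± 7.28, and innate lymphoid cells 0.532% ± 0.237 and 0.955% ± 0.350 (SD, n = 6 each). Macrophages made up 56.3% ± 23.1 after CLP and 64.2% ± 17.5 in controls (SD, n = 6 each).

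None of the 9 class shares passed adjustment. The exact permutation p (two-sided, n = 6 per group, within batches) was 0.0190 for neutrophils, 0.0286 for dendritic cells, 0.0476 for innate lymphoid cells, 0.0619 for monocytes and 0.0619 for B cells. The adjusted p was 0.111 for each of these classes. The neutrophil share was above every control library of the same batch in 5 of the 6 CLP libraries. Within batches, neutrophils were 12.4% after CLP and 4.35% in controls in batch A (exact permutation p = 0.114) and 39.3% and 21.1% in batch B. CLP replicate 6 held more neutrophils (43.9%) than macrophages (31.1%), and CLP replicate 5 fewer (34.8% and 37.7%). Monocytes were 7.03% and 2.11% in batch A and 7.01% and 3.34% in batch B. Dendritic cells were 3.42% and 4.62% in batch A and 3.73% and 7.52% in batch B. B cells were 3.38% and 6.02% in batch A and 10.4% and 17.8% in batch B. CLP replicate 4 held the largest monocyte share, 19.0%, and the largest neutrophil share of batch A, 26.2%, where the other CLP libraries had 2.46% to 13.2%. The exact permutation p was 0.333 for macrophages, 0.219 for NK cells (2.21% after CLP and 3.16% in controls), 0.586 for T cells (3.18% and 3.64%) and 0.310 for mast cells or basophils (0.161% and 0.0721%), a class in which no assignment can give less than 0.0714.

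**Figure D1:**
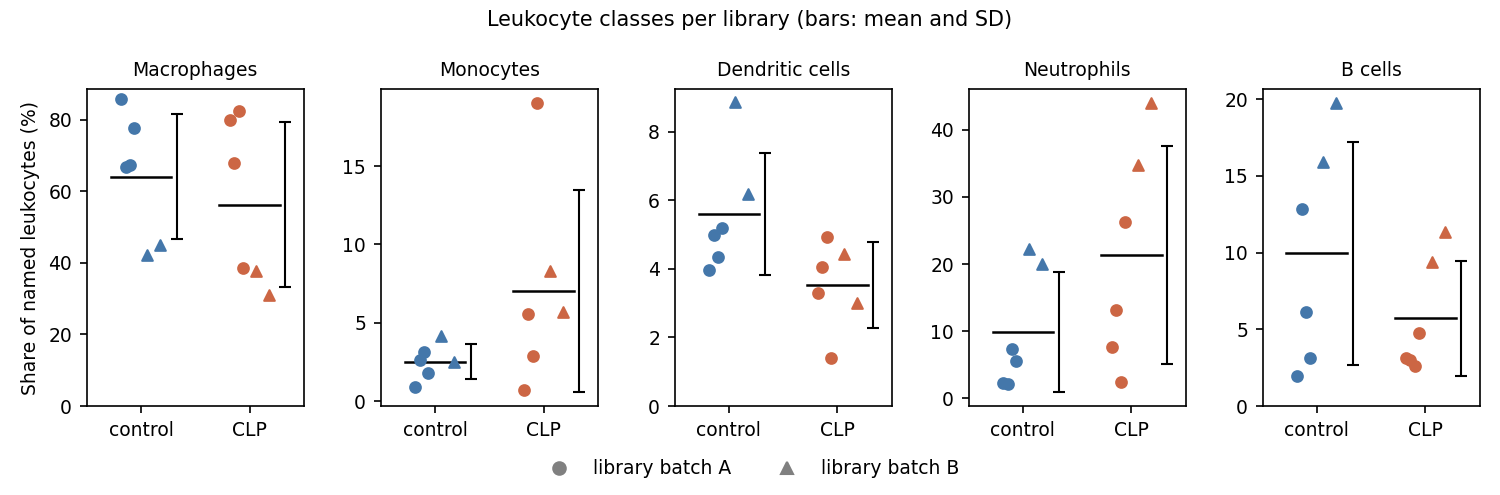
Share of named leukocytes (%) per library for 5 classes, in control and CLP hearts. Circles are libraries of batch A and triangles of batch B, the line is the mean and the bar beside it the SD of the 6 libraries. Mean neutrophil shares are 9.94% in controls and 21.4% after CLP, and batch B lies above batch A in both groups.

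Macrophages of CLP hearts carried less Slc40a1 mRNA, which encodes ferroportin, the only known cellular iron exporter. Its level fell from 163 ± 63.4 CPM in controls to 50.2 ± 29.5 CPM after CLP (SD, n = 6 each), a log2 fold change of -1.69 (SE 0.21, edgeR adjusted p = 0.00735). Each of the 6 CLP libraries lay below every control library of its batch. Cfb, which encodes complement factor B of the alternative pathway, rose from 6.21 ± 1.82 to 22.6 ± 14.5 CPM (log2 fold change 1.67, SE 0.28, edgeR adjusted p = 0.0458), with each of the 6 CLP libraries above every control library of its batch. Retnlg, a gene characteristic of neutrophils, rose from 3.93 ± 4.35 to 25.1 ± 38.6 CPM (log2 fold change 2.63, SE 0.42, edgeR adjusted p = 0.0458), with 5 of the 6 CLP libraries above every control library of their batch. B cells carried Retnlg at 2.23 and 2.30 times the macrophage level in CLP replicates 5 and 6, but none in CLP replicates 2, 3 and 4, and S100a8, S100a9 and Retnlg together at a median of 2.01 times over these 5 libraries. CLP replicate 6 held 101 CPM of Retnlg and set its mean.

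In all, 3 of 9805 genes tested rose (Cfb, Retnlg and 1 predicted gene) and 1 fell. Of the other genes named by the lowest p, which did not pass, C4b, encoding a complement C4 protein of the classical pathway, had 99.8 ± 31.8 CPM in controls and 202 ± 66.3 after CLP (log2 fold change 0.99, edgeR adjusted p = 0.0589), higher in 6 of 6 CLP libraries than in every control library of the batch. Cd38, an enzyme that breaks down NAD, had 63.8 ± 10.1 and 113 ± 33.6 CPM (log2 fold change 0.80). Ubald2 had a log2 fold change of 0.62. Zfp395 (-0.61), Frmd6 (-1.04), Mtus1 (-0.77) and Bhlhe41 (-0.74), a transcription repressor of the circadian clock family, had negative log2 fold changes. The adjusted p of these 6 genes was 0.0755. The genes lie on mm10 at chromosome 1, 45908068 to 45926523 (Slc40a1, ENSMUSG00000025993), chromosome 17, 34856374 to 34862518 (Cfb, ENSMUSG00000090231) and 34728380 to 34743882 (C4b, ENSMUSG00000073418), and chromosome 16, 48872621 to 48874496 (Retnlg, ENSMUSG00000022651). Slc40a1 had log2 fold changes of -1.74 in batch A (adjusted p = 0.0381) and -1.59 in batch B (adjusted p = 0.104), and Cfb of 2.04 (adjusted p = 0.0490) and 1.11 (adjusted p = 0.255). Their CLP difference did not differ between batches by the interaction test (adjusted p = 0.938 and 0.660).

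At an unadjusted p under 0.05 there were 800 macrophage genes higher and 689 lower, and DESeq2 called 71 higher and 53 lower. The count of macrophage genes higher was 0 without control replicate 2, 3, 4 or 5 or CLP replicate 3 or 4, 1 without control replicate 1 or 6, 5 without CLP replicate 2 or 5, 49 without CLP replicate 1, and 0 without both CLP replicates 5 and 6, whereas Slc40a1 passed in each of these fits. The macrophage gene Cfb did not pass without control replicate 1, 2, 3, 4 or 5 or CLP replicate 3, 4 or 5 (edgeR adjusted p between 0.0574 and 0.180). The macrophage gene Retnlg did not pass without any 1 control replicate or without CLP replicate 3, 4 or 6 (between 0.0510 and 0.239). The count of macrophage genes lower was 53 without CLP replicate 1 and 2 without CLP replicate 6.

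**Figure D2:**
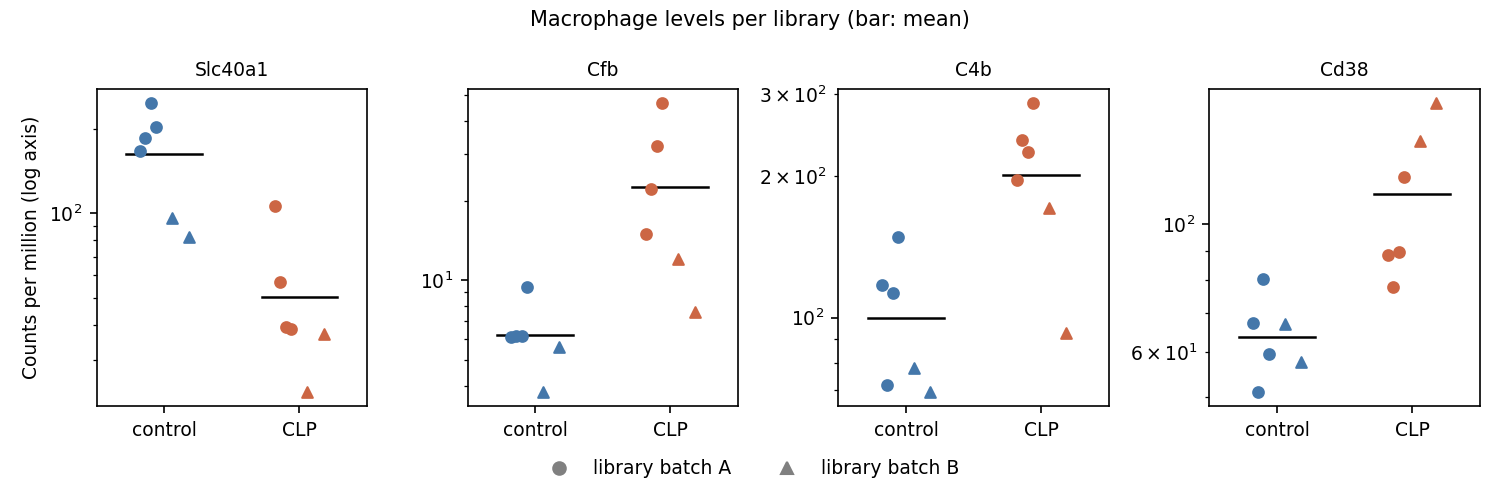
Macrophage levels of Slc40a1, Cfb, C4b and Cd38 per library in CPM on a log axis, in control and CLP hearts. Circles are libraries of batch A, triangles of batch B, and the bar is the mean. Slc40a1 has a mean of 163 CPM in controls and 50.2 CPM after CLP, and Cfb of 6.21 and 22.6 CPM.

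Of the 24 gene lists with enough measured genes in macrophages, 12 moved up and 0 moved down by camera with the preset correlation. With an estimated correlation 0 lists passed (lowest adjusted p = 0.137), and fry called 2, glycolysis and alarmins. Since the genes within a list rise and fall together from library to library, the preset correlation overstates how sure these calls are.

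The complement list, the plasma proteins that tag microbes and debris, had a median log2 fold change of 0.29 over 15 genes, of which Cfb rose and 4 passed adjusted over the list alone (adjusted p = 4.81e-05, and 0.232 with an estimated correlation). Its most abundant members, the C1q chains of the classical pathway, had log2 fold changes of 0.37 (C1qa), 0.45 (C1qb) and 0.26 (C1qc) and did not pass. The list of NF-kB and TNF inflammatory genes had a median of 0.94 over 27 genes, 0 past the threshold (edgeR, 1489 of all genes at an unadjusted p under 0.05) and 13 higher adjusted over the list alone (adjusted p = 2.39e-10, and 0.380 with an estimated correlation). Its medians were 0.34 in batch A and 1.82 in batch B, and the batches differed by the interaction test (adjusted p = 1.69e-09, and 0.839 with an estimated correlation). Nfkbia, the inhibitor that NF-kB itself induces, had 192 ± 63.4 CPM in controls and 583 ± 483 after CLP (log2 fold change 1.40, adjusted p = 0.120). The endotoxin co-receptor gene Cd14 had a log2 fold change of 0.50 and the cytokine gene Il1b one of 0.30. Chemokines, which attract leukocytes, had a median of 1.02 over 18 genes, with 1 higher adjusted over the list alone (adjusted p = 0.000140, and 0.344 with an estimated correlation). Ccl6 (log2 fold change 0.44), Ccl9 (0.56) and Cxcl16 (0.32) are its most abundant members.

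Alarmins and neutrophil granule genes had a median of 1.18 over 6 genes, of which Retnlg rose and 5 passed adjusted over the list alone (adjusted p = 3.51e-06, and 0.137 with an estimated correlation). S100a9 and S100a8, the subunits of calprotectin, had log2 fold changes of 2.21 (adjusted p = 0.0755) and 1.75 (adjusted p = 0.146), and Wfdc17 one of 0.61. Monocyte-derived macrophage genes had a median of 0.34 over 18 genes, 6 of them higher adjusted over the list alone (adjusted p = 4.81e-05, and 0.305 with an estimated correlation). The lysozyme gene Lyz2 (log2 fold change 0.37), Ifi27l2a (0.39) and Crip1 (0.24) lead it by level. Glycolysis genes had a median of 0.19 over 18 genes, 6 higher adjusted over the list alone (adjusted p = 0.000241, and 0.137 with an estimated correlation), led by Gapdh (log2 fold change 0.38), Gpi1 (0.13) and Aldoa (0.32). Cytosolic ribosomal proteins had a median of 0.28 over 81 genes (adjusted p = 1.44e-15, and 0.527 with an estimated correlation), and oxidative phosphorylation genes, led by Cox4i1 (log2 fold change 0.27), Cox7c and Cox8a, one of 0.22 over 75 genes (adjusted p = 2.82e-09, and 0.615 with an estimated correlation). Both lists were nearer to 0 in batch B, at 0.11 and 0.0097, than in batch A, at 0.37 and 0.34. No single gene passed in either list, nor adjusted over the list alone. Neither rise was particular to macrophages by camera at the preset correlation. Ribosomal proteins moved up in B cells, monocytes, neutrophils, NK cells and T cells (medians 0.49, 0.34, 0.38, 0.35 and 0.31). Oxidative phosphorylation genes moved up in B cells, dendritic cells, monocytes, NK cells and T cells (0.26, 0.11, 0.36, 0.33 and 0.29). With an estimated correlation neither list passed in any of these classes.

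Interferon gamma response genes had a median of 0.26 over 19 genes, led by Ciita (log2 fold change -0.53), Gbp7 (0.22) and Irf1 (0.79), with 1 higher adjusted over the list alone (adjusted p = 0.0150, and 0.615 with an estimated correlation). The median of this list was 0.032 in batch A and 0.40 in batch B (interaction test, adjusted p = 0.00269, and 0.839 with an estimated correlation). MHC class I genes, which present peptides to CD8 T cells, had a median of 0.20 over 17 genes (adjusted p = 0.0150, and 0.615 with an estimated correlation), with log2 fold changes of 0.12 for B2m and 0.33 for H2-D1 and H2-K1. Dissociation stress genes had a median of 0.18 over 35 genes (adjusted p = 0.0298, and 0.647 with an estimated correlation), led by Hsp90ab1, Hspa8 and Hsp90aa1 (log2 fold changes 0.18, 0.16 and 0.18). Cardiomyocyte genes, a measure of free RNA in this gate, had a median of 0.37 over 13 genes (adjusted p = 0.00167, and 0.380 with an estimated correlation), 0.0735 in batch A and 0.74 in batch B.

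The remaining 12 lists did not pass. Resident macrophage genes had a median of 0.0062 over 23 genes (adjusted p = 0.962), with Selenop, Pf4 and F13a1 at log2 fold changes of -0.07, 0.14 and 0.01. MHC class II genes had a median of 0.29 over 9 genes (adjusted p = 0.0966), with Cd74 at 0.37, H2-Aa at 0.34 and H2-Ab1 at 0.36. Type I interferon genes had a median of 0.03 over 34 genes (adjusted p = 0.679), and phagocytosis and efferocytosis genes 0.01 over 27 (adjusted p = 0.566). Lysosome and lipid handling genes had a median of 0.10 over 32 (adjusted p = 0.238), growth factors and matrix remodelling -0.01 over 22 (adjusted p = 0.746) and cell cycle genes 0.09 over 18 (adjusted p = 0.223). The cell cycle median was 0.28 in batch A and -0.21 in batch B (interaction test, adjusted p = 6.54e-06, and 0.295 with an estimated correlation). The hypoxia and haem handling list had a median of -0.0012 over 18 genes and a mean of 0.05 (adjusted p = 0.962), camera giving it as down and fry as up. It holds Slc40a1, which fell, while the ferritin genes Fth1 and Ftl1, which store iron, had log2 fold changes of 0.41 and 0.26, and 2 members were higher and 2 lower adjusted over the list alone. Mitochondrially encoded genes had a median of 0.03 over 13 genes (adjusted p = 0.912), sex-linked genes -0.05 over 4 (adjusted p = 0.244), B cell genes -0.31 over 4 (adjusted p = 0.0985) and endothelial genes 0.33 over 3 (adjusted p = 0.475). Too few genes of the haemoglobin, T cell and fibroblast lists were measured in macrophages for a test.

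**Figure D3:**
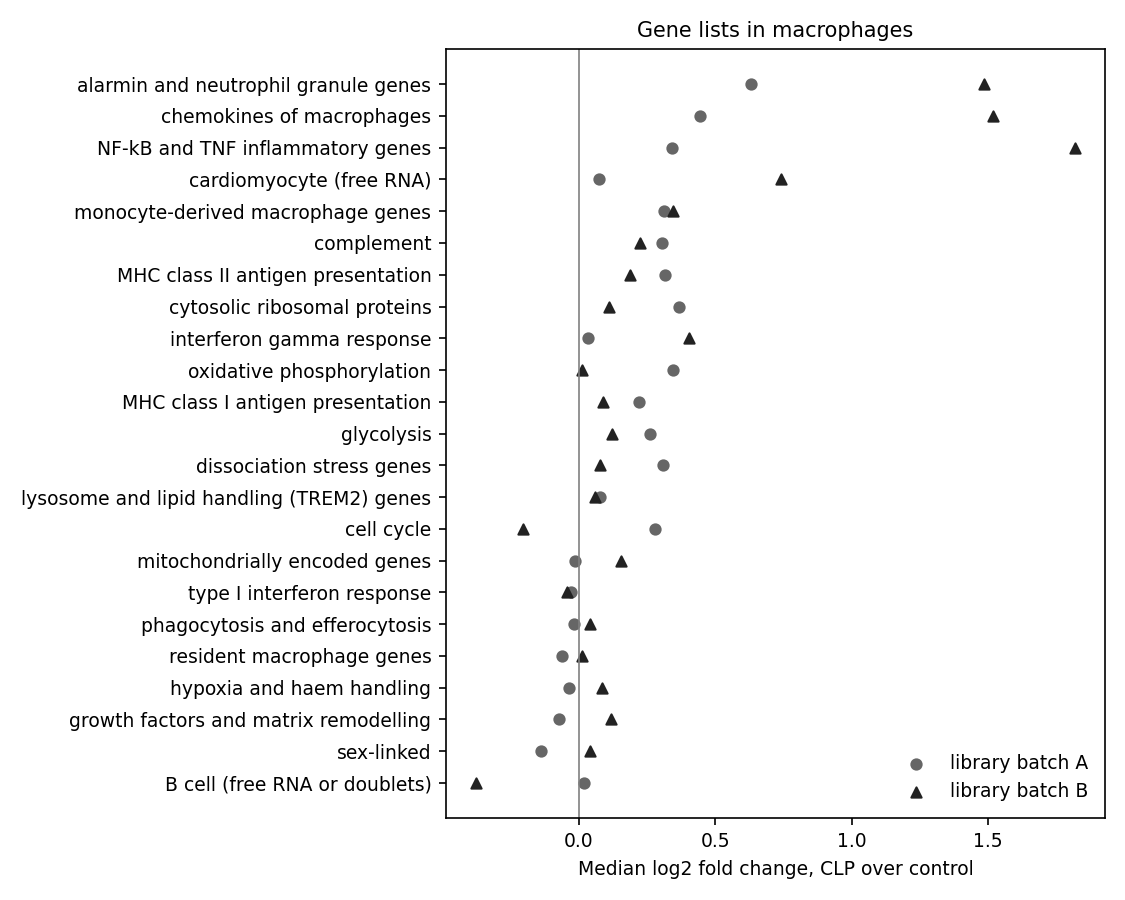
Median log2 fold change of each gene list in macrophages, CLP over control, in library batch A (circles) and library batch B (triangles), for the lists measured in both. The NF-kB and TNF inflammatory genes lie at 0.34 in batch A and 1.82 in batch B.

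The macrophages of CLP replicates 5 and 6 stood apart from those of every other library. A cluster led by Ch25h, which makes an antiviral oxysterol, the metallothionein Mt2 and the monocyte attractants Ccl12, Ccl7 and Ccl2 held 85.1% and 93.7% of their macrophages and at most 2.66% in any other library. In batch B, CLP macrophages carried 722 CPM of Socs3, an inhibitor of cytokine signalling, against 20.5 CPM in controls. They carried 738 against 31.0 CPM of Mt2, and 425 against 56.2 CPM of Ccl2 (n = 2 per group). Ccl2 was 69.3 CPM in CLP replicate 5 and 781 CPM in CLP replicate 6. In batch A, the means were 64.0 against 36.2 CPM for Socs3, 65.9 against 43.5 CPM for Mt2 and 64.8 against 67.4 CPM for Ccl2 (n = 4 per group). The difference between the batches was past the threshold for 12 genes by the edgeR interaction test, all with a greater rise in batch B, among them Socs3 (log2 fold change 0.81 in batch A and 5.14 in batch B), Mt2 (0.60 and 4.58) and Sbno2 (0.19 and 3.297). These genes were named after their values were seen.

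**Figure D4:**
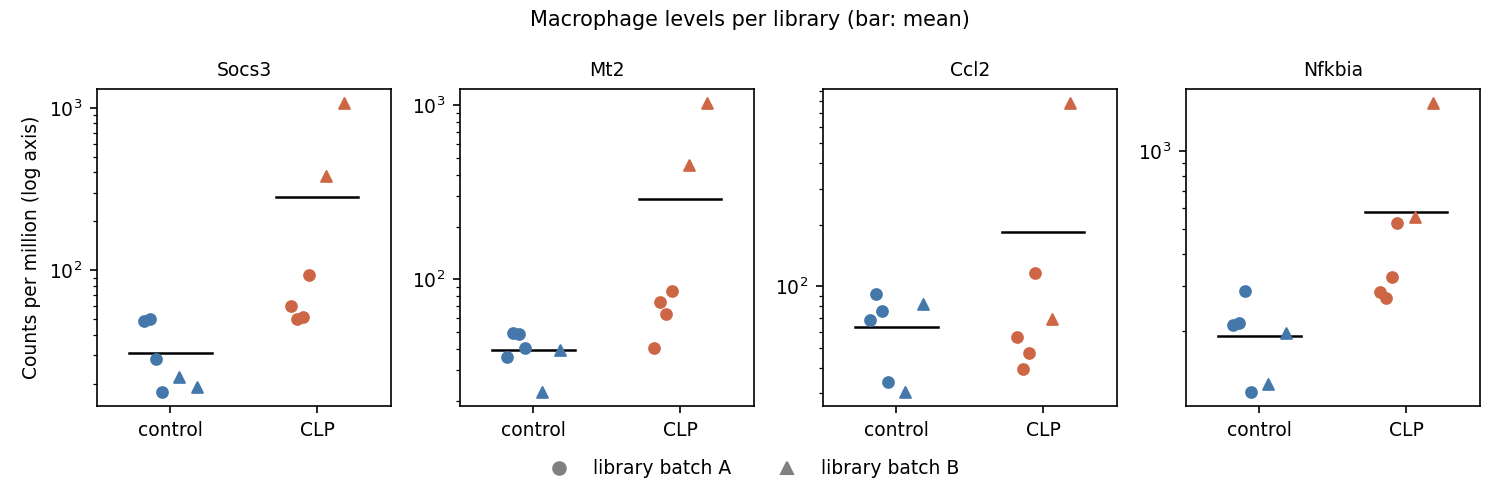
Macrophage levels of Socs3, Mt2, Ccl2 and Nfkbia per library in CPM on a log axis, in control and CLP hearts. Circles are libraries of batch A, triangles of batch B, and the bar is the mean. In batch B the means of Socs3 are 20.5 CPM in controls and 722 CPM after CLP.

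None of the 12 macrophage marker shares passed, which does not show that they are alike, and the means over both batches can hide shifts. Cd163 at 1000 UMIs was detected in 35.3% and 32.3% of macrophages in CLP replicates 5 and 6, against 28.7% and 25.3% in control replicates 5 and 6. In batch A its share was 35.6% to 43.8% after CLP and 38.9% to 49.1% in controls. Il1b was detected in 11.8% in CLP replicate 5 and 40.8% in CLP replicate 6. After thinning to 1000 UMIs, Lyve1, a hyaluronan receptor of resident macrophages, was detected in 35.6% ± 8.70 of CLP and 33.4% ± 11.2 of control macrophages, the folate receptor gene Folr2 in 36.3% ± 8.77 and 33.8% ± 7.49, and the phosphatidylserine receptor gene Timd4 in 7.13% ± 2.36 and 8.33% ± 2.20 (SD, n = 6 each). Ccr2, the receptor that brings monocytes into tissue, was detected in 5.33% ± 1.47 and 5.52% ± 2.34. Cd163 was detected in 38.0% and 38.4%, H2-Aa in 70.7% and 68.9%, Cd74 in 80.9% and 79.0%, Il1b in 16.8% and 17.6%, Trem2 in 13.3% and 12.9%, Spp1 in 0.442% and 0.594% and Mki67 in 0.759% and 0.728% of CLP and control macrophages. The interferon-induced Isg15 was detected in 3.29% ± 1.11 of CLP and 2.35% ± 0.719 of control macrophages (exact permutation p = 0.0381, adjusted p = 0.457, n = 6 each), and the other 11 genes had an adjusted p of 0.962. B cells at the same depth had Lyve1 in 1.24% of CLP and 0.689% of control cells, Ccr2 in 0.383% and 0.439%, and Isg15 in 0.693% and 0.346%. H2-Aa and Cd74 are B cell genes as well, so B cells give no background for them. Median depth before thinning was 3442 UMIs in CLP and 4963.5 UMIs in control macrophages, and 2173 and 3027.5 UMIs in B cells. The marker shares leave out 510 of 5307 CLP and 210 of 4074 control macrophages, which had fewer than 1000 UMIs. In CLP replicate 3 they rest on 1088 of 1473 macrophages.

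Re-clustered macrophages gave a resident subset defined by Timd4, Lyve1 and Folr2, an MHC class II-high subset and an interferon subset, and the shares of none of them passed. The resident subset made up 21.2% ± 17.4 of CLP and 30.7% ± 11.996 of control macrophages (exact permutation p = 0.105, adjusted p = 0.210, n = 6 each), 31.4% and 36.4% in batch A and 0.919% and 19.2% in batch B. The MHC class II-high subset made up 1.62% and 14.3% (exact permutation p = 0.176, n = 6 each), 2.18% and 2.15% in batch A and 0.504% and 38.7% in batch B. Its size depended on the resolution. It held 906 cells at 0.5 (89.5% from batch B), 2545 at 0.3 (55.8%) and 853 at 0.8 (90.2%). Its low share in batch A does not mean that few macrophages there carried such genes. H2-Aa was detected at 1000 UMIs in 55.7% to 79.9% of macrophages per library of batch A. The interferon subset made up 1.28% and 1.76% (exact permutation p = 0.238), and sub-clusters without a name 75.9% and 53.2% (exact permutation p = 0.0810, n = 6 each). One of the latter, with 1992 cells, held 1193 cells of CLP replicate 5, 748 of CLP replicate 6 and at most 10 of any other CLP library. Low subset shares in CLP replicates 5 and 6 thus do not show a loss of such macrophages, since the markers stayed detected. At 1000 UMIs, Lyve1 was found in 31.3% and 21.6% of their macrophages, against 23.1% and 22.4% in control replicates 5 and 6. Folr2 was found in 28.9% and 23.9% against 27.1% and 23.9%, Timd4 in 5.44% and 4.65% against 8.21% and 4.30%, and H2-Aa in 77.2% and 81.7% against 80.3% and 82.4%. No sub-cluster could be named for the CCR2 or TREM2 subset.

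Monocytes had 133 genes higher and 101 lower among 6021 tested in 5 CLP and 3 control libraries. The class joins cluster 8, led by Ace, Cd300e and Ear2 (602 cells, 74.3% from CLP libraries), and cluster 16, led by Vcan, Chil3 and Fn1 (492 cells, 88.2%). Of the monocytes, cluster 16 held 170 of 292 in CLP replicate 5 and 80 of 146 in CLP replicate 6, but 34 of 108 in control replicate 5 and 14 of 54 in control replicate 6. The calls can therefore include a change in the mix of the clusters. In cluster 8 alone 326 genes passed, 120 of them among the 234 of the class. Of the controls, only replicates 5 and 6 held at least 20 cells of cluster 8, fewer than the minimum of 3 libraries per group. With no control library in batch A, that fit compares the groups within batch B only. Ms4a6d, a membrane gene of monocytes and macrophages, rose from 56 ± 20.1 to 339 ± 159 CPM (log2 fold change 2.90, SE 0.36, edgeR adjusted p = 0.00102). Tarm1, an activating receptor of myeloid cells (log2 fold change 4.73, adjusted p = 0.000125), and the glucose transporter gene Slc2a1 (2.73, adjusted p = 0.00165) rose too, as did the acute-phase gene Saa3, from 2.37 ± 4.10 to 588 ± 1101 CPM (adjusted p = 0.00102). CLP replicate 6 held 2545.5 CPM of Saa3 and set its mean, with at most 308 CPM in the other CLP libraries. Klf4, a transcription factor of monocyte development (log2 fold change -1.70, adjusted p = 0.00274), the chloride transporter gene Slc12a2 (-2.39, adjusted p = 0.000870), Arrdc3 (-3.304, adjusted p = 0.00270), Mbp (-1.71, adjusted p = 0.00482) and Mdm1 (-2.12, adjusted p = 0.00552) fell. For each of these 9 genes, all 5 CLP libraries lay beyond every control library of their batch, but batch A holds a single control library with enough monocytes.

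By list, 13 of 22 lists moved up in monocytes by camera and 0 down, and 0 passed with an estimated correlation. NF-kB and TNF inflammatory genes had a median log2 fold change of 2.03, with 8 of 25 higher and 17 higher adjusted over the list alone (adjusted p = 5.80e-10, and 0.345 with an estimated correlation). Among those past the threshold were Cxcl2, a neutrophil attractant (log2 fold change 5.83), the adhesion gene Icam1 (3.22), the pattern receptor gene Tlr2 (2.48) and the superoxide dismutase gene Sod2 (2.57). Chemokines had a median of 1.91, with Cxcl2, Cxcl10 and Ccl9 higher of 9 and 5 adjusted over the list alone. Alarmins had one of 1.96, with Mmp8, Wfdc17 and Lcn2 higher of 10 and 7 adjusted over the list alone, and complement genes one of 1.58, with C1qb higher and Itgax lower of 11 and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.312 for each of the 3 with an estimated correlation). Part of this RNA may come from other cells, which was not tested. Resident macrophage genes had a median of 1.08 in monocytes (adjusted p = 0.000133, and 0.344 with an estimated correlation), Lcn2, Mmp8, Tarm1 and C1qb were called higher in neutrophils too, and alarmins moved up in T cells as well (adjusted p = 0.000429, and 0.408 with an estimated correlation). The members were named after their values were seen. Without CLP replicates 5 and 6 the count of monocyte genes past threshold was 8, without control replicate 5 it was 6, and without control replicate 6 it was 57. Without CLP replicate 5 it was 129, without CLP replicate 6 it was 139 and without control replicate 3 it was 385. The fit without control replicate 3 had no control library in batch A and so compares the groups within batch B only. Without a batch term it was 0. Without control replicate 5, neither Slc2a1, Mbp and the monocyte gene Saa3 (adjusted p = 0.0562 each) nor the monocyte gene Mdm1 (adjusted p = 0.113) passed.

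Neutrophils had 38 genes higher and 4 lower among 2517 tested in 6 CLP and 5 control libraries. In batch B the groups lay in different clusters. Of the neutrophils, a cluster led by Mmp9 held 534 of 574 in control replicate 5 and 371 of 435 in control replicate 6, a cluster led by Il1r2 1019 of 1220 in CLP replicate 5, and a cluster led by Il23a 801 of 1124 in CLP replicate 6. The calls can come from such a change of clusters. The alarmin and granule list had a median of 1.10, with 6 of 14 higher and 9 adjusted over the list alone (adjusted p = 0.0832 with an estimated correlation). Of its members, named after their values were seen, Ngp had 23.2 ± 34.4 CPM in controls and 1610 ± 1876 CPM after CLP (log2 fold change 5.49, adjusted p = 0.00903), and Camp (5.18, adjusted p = 0.0276), Lcn2 (1.65, adjusted p = 0.0311) and Mmp8 (1.47, adjusted p = 0.0138) rose too. MHC class II genes were at a median of 1.69 and 4 of 5 higher, 5 adjusted over the list alone (adjusted p = 0.0832 with an estimated correlation). Of the macrophage lists, resident macrophage genes had 1 of 4 higher and 4 adjusted over the list alone (adjusted p = 0.155 with an estimated correlation), and monocyte-derived macrophage genes 1 of 15 and 6 (adjusted p = 0.131 with an estimated correlation). Complement genes were at 0.72 with C1qa, C1qb and C1qc higher of 7 and 4 adjusted over the list alone (adjusted p = 0.0615 with an estimated correlation). Apoe, which carries lipids, rose from 497 ± 81.7 to 1889 ± 1156 CPM (log2 fold change 1.97, adjusted p = 0.00903). Macrophages held a mean of 22350 CPM of Apoe after CLP and 17668 CPM in controls (n = 6 each). C1qb was called higher in monocytes and NK cells too, and Apoe in NK cells. Part of the C1q, Apoe and MHC class II RNA in neutrophils may come from other cells, which was not tested.

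By the naming rule, Adpgk, a glycolytic kinase gene (log2 fold change 4.27, adjusted p = 0.00134), Klhdc4 (1.99), Gyg, the primer of glycogen synthesis (1.64), and Mrgpra2b (2.63) rose in neutrophils, and Arhgap5 (-1.75), with an adjusted p of 0.00903 each, Mbp (-0.95, adjusted p = 0.0360), Zfp710 (-1.24, adjusted p = 0.0420) and Rab11fip4 (-1.09, adjusted p = 0.0461) fell. Each of these calls was lost without 1 or more of control replicates 1, 3, 4, 5 and 6 or CLP replicates 1, 2, 3, 4 and 6, except that Klhdc4 passed in each of the 6 such fits that measured it. Of the 6 CLP libraries, 4 lay above every control library of their batch for Adpgk and 5 below for Arhgap5. In all 13 of 19 lists moved up and 1, the type I interferon response, down (median -0.24, adjusted p = 0.284 with an estimated correlation), and fry called 9. Mitochondrially encoded genes, which also follow the state of the cells, were among those up, with a median of 0.72, 1 of 11 higher and 8 adjusted over the list alone (adjusted p = 0.146 with an estimated correlation and 0.0451 by fry). A neutrophil cluster led by Camp, Ngp and Ltf took 83.8% of its cells from CLP replicate 6. The count of neutrophil genes past threshold was 0 without CLP replicate 6, without control replicate 5 or without both CLP replicates 5 and 6, 4 without CLP replicate 4, 13 without control replicate 6, 66 without CLP replicate 3, 89 without CLP replicate 1, 98 without control replicate 3 and 102 without control replicate 4.

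In conventional dendritic cells 17 genes were higher and 2 lower among 3467 tested (5 libraries per group). Fkbp5, a chaperone gene induced by glucocorticoids, rose from 21.6 ± 20.4 to 105 ± 56.4 CPM (log2 fold change 2.75, SE 0.43, edgeR adjusted p = 0.0107), with 4 of 5 CLP libraries above every control library of their batch. Rab3il1 (log2 fold change 1.41, adjusted p = 0.0107), the interleukin 4 receptor gene Il4ra (1.89), the autophagy gene Vmp1 (0.99) and the corepressor gene Tle3 (1.49) also rose, and Hpgd, which breaks down prostaglandins (-1.30, adjusted p = 0.0200), and P2ry10 (-1.12, adjusted p = 0.0257) fell. Of 20 lists 3 moved up (alarmins, oxidative phosphorylation and lysosome genes) and 0 down, with 0 past the threshold by an estimated correlation. The count of conventional dendritic cell genes past threshold was 0 without CLP replicates 5 and 6, 0 without control replicate 6, 1 without control replicate 5, 5 without CLP replicate 5, 29 without CLP replicate 3, 30 without CLP replicate 4, 31 without CLP replicate 2 and 40 without control replicate 3. It was 0 without a batch term. None of the 7 genes named passed without control replicate 5 or 6, with the highest adjusted p, 0.284, for the conventional dendritic cell gene Il4ra. Hpgd, Vmp1 and P2ry10 did not pass without CLP replicate 5 either, nor the conventional dendritic cell gene P2ry10 without CLP replicate 6 (adjusted p = 0.0673).

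In NK cells 9 genes were higher and 1 lower among 2766 tested (4 libraries per group). The protease inhibitor gene Serpina3g (log2 fold change 1.86, edgeR adjusted p = 0.00356), Nfkbia (2.24), the stress gene Gadd45b (3.34) and the AP-1 gene Junb (1.23) rose, and the heat-shock gene Hspa1b fell (-2.21, adjusted p = 0.0274). Serpina3g was above every control library of its batch in 4 of 4 CLP libraries and Hspa1b below in 2 of 4. Lyz2, a gene of myeloid cells, rose from 265 ± 110 to 1339 ± 643 CPM (log2 fold change 2.09, adjusted p = 0.00356), where macrophages held 13873 CPM after CLP. Of 20 lists 11 moved up, none of them with an estimated correlation (lowest adjusted p = 0.278). The count of NK cell genes past threshold was 1 without a batch term, 2 without control replicate 5, 5 without control replicate 3, 6 without control replicate 6, 17 without CLP replicate 5 and 20 without CLP replicate 2. Without control replicate 5 the genes Serpina3g, Nfkbia, Gadd45b and Junb did not pass. Nor did Nfkbia without control replicate 6, Gadd45b without CLP replicate 4, Junb without control replicate 1, 3 or 6 or CLP replicate 6, and Hspa1b without control replicate 1, 3 or 6 or CLP replicate 4 (adjusted p at most 0.304, for the NK cell gene Junb).

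In B cells 0 of 1782 genes passed by edgeR (5 libraries per group), with 231 at an unadjusted p under 0.05 and 2 called by DESeq2. Cytosolic ribosomal proteins had a median log2 fold change of 0.49 there, with 61 of 79 higher adjusted over the list alone and 0 over all genes (adjusted p = 0.413 with an estimated correlation). In T cells 0 of 3343 genes passed by edgeR (5 CLP and 4 control libraries), with 286 at an unadjusted p under 0.05 and 2 called by DESeq2. In each of these classes 6 lists moved up by camera and 0 down, with 0 past the threshold by an estimated correlation. The count of B cell genes past threshold was 9 without control replicate 3, 4 without CLP replicate 4, 2 without control replicate 2 and 1 without CLP replicate 2 or 6, and that of T cell genes past threshold was 7 without control replicate 4 and 1 without control replicate 3 or 6 or CLP replicate 5 or 6.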

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

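The tests of batch, of an effect alike in all CLP libraries, of dissociation stress, of free neutrophil RNA, of the level expected from cluster shares, of B cells alone for Slc40a1 and of other splits of the libraries were chosen only after the result was seen, and the tests of joined droplets, of levels within clusters and of free Slc40a1 RNA were fixed before.

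The first pattern is the macrophage cluster led by Ch25h, Mt2 and Ccl2 that held 85.1% and 93.7% of the macrophages of CLP replicates 5 and 6, and with it the 12 macrophage genes and 7 macrophage gene lists whose CLP difference differed between the batches by the interaction test. The batch B controls had at most 2.66% of their macrophages in it and CLP replicates 1 to 4 at most 2.03%, but these values restate how the cluster was found and so do not test a difference between the library batches or an effect of CLP alike in all libraries. A rise of the dissociation stress genes as a whole is argued against by a median log2 fold change of 0.0786 for the 35 genes in batch B (interquartile range 1.51, 18 above 0). The 27 NF-kB and TNF genes tested over both batches had 1.92 there (interquartile range 1.58, 27 above 0, and 1.82 over all those measured in batch B). The stress list holds Socs3, which rose in batch B, so stress that raises only some of its genes stays open. A more severe or later infection in these mice, a different handling of these 2 hearts and wrong labels stay open and were not tested, so the pattern may be biological or technical. None of the 7 lists differed between batches with an estimated correlation. The macrophages of CLP replicates 5 and 6 were also not all alike. Re-clustering at resolution 0.8 gave a sub-cluster led by Ddit4 with 89.7% of its 1266 cells from CLP replicate 5. Another, led by Cxcl10, had 86.7% of its 744 cells from CLP replicate 6.

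The second pattern is the neutrophil transcripts in CLP macrophages, where Retnlg reached 101.34 CPM in CLP replicate 6, far above the other CLP libraries (1.47 to 29.3 CPM). B cells held S100a8, S100a9 and Retnlg at a median of 2.01 times the macrophage level over 15 tests, in line with free RNA from neutrophils, although the B cells of CLP replicate 3 (54065 UMIs) held none of the 3 genes and those of CLP replicates 2 and 4 no Retnlg, which leaves the source open there. In CLP replicate 5 the macrophages had a UMI of these genes in 91.7% of cells and the B cells in 91.2%, and in CLP replicate 6 in 99.1% and 99.3%, at median depths of 7428 and 3003 UMIs and of 6055 and 2501 UMIs. Retnlg per S100a9 was 0.132 in macrophages, 0.146 in B cells and 0.145 in neutrophils of CLP replicate 5, and 0.184, 0.198 and 0.202 in CLP replicate 6. In CLP replicates 5 and 6, the spread over cells argues against macrophages joined with a neutrophil in 1 droplet as the main source. The top 5% of macrophages held 21.8% of these UMIs in CLP replicate 5 and 11.2% in CLP replicate 6. Joined droplets were not tested in CLP replicates 1 to 4 and stay open there.

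The third pattern is the lower Slc40a1 level in CLP macrophages, for which a direct effect of infection or surgery on ferroportin expression stays open, untested. By the bound fixed beforehand a lower share of the clusters that express it can be neither excluded nor shown, because within batch A the log2 ratio of CLP to control was -1.87 in cluster 0 and -2.21 in cluster 1 (exact permutation p = 0.0286 each, two-sided, the smallest possible), but -0.88 in cluster 2 and -0.17 in cluster 4 (mean -1.28). In a later test, run on batch A only, the cluster shares alone gave an expected log2 ratio of -0.13 where -1.81 was observed. This argues against cluster shares as the main cause in batch A. The test was not run in batch B, where the cluster led by Ch25h held 88.3% of CLP and 2.08% of control macrophages. Cluster shares as a cause of the lower Slc40a1 level stay open there. A shift among cells within clusters stays open in both batches. The test of free RNA fixed beforehand pooled B cells and neutrophils and gave a median of 1.11 times the macrophage level over 10 tests, which by the bound written for it would have counted for free RNA, but it is void, because the neutrophils carried more Slc40a1 than the macrophages in each of 5 control libraries (2.15 to 5.00 times). A later test on B cells alone gave a median of 0.0153 times the macrophage level (0 to 0.0682 over 5 libraries), which argues against free RNA that reaches B cells and macrophages alike.

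Of 122 groups tested for a library far from the others, 11 held one, where chance gives about 1 in 20. Besides Retnlg, the mast cell or basophil share of control replicate 6 was 0.3226% (other controls at most 0.110%). Il1b was detected in 40.7908% of macrophages of CLP replicate 6 (7.44% to 17.3% in other CLP libraries; B cells 6.37% after CLP and 2.47% in controls; median depths 3442 and 4963.5 UMIs in macrophages and 2173 and 3027.5 UMIs in B cells). The interferon subset made up 2.2403% of macrophages in CLP replicate 3 (0.879% to 1.36% in the others). Hpgd was 179.71 CPM in dendritic cells of CLP replicate 4 (79.5 to 95.6 CPM in the others), and Saa3 was 2545.5 CPM in monocytes of CLP replicate 6 (12.4 to 308 CPM). In neutrophils, Adpgk was 472.69 CPM in CLP replicate 6 (0 to 133 CPM), Gyg 103.09 CPM in control replicate 1 (12.8 to 29.9 CPM), Arhgap5 154.61 CPM in CLP replicate 1 (31.2 to 44.5 CPM), Mbp 492.47 CPM in control replicate 4 (258 to 282 CPM) and Rab11fip4 124.75 CPM in CLP replicate 3 (33.8 to 51.0 CPM). The CLP difference also differed between batches for 10 genes in dendritic cells, for 1 in neutrophils (Tnfaip3) and for 1 in T cells (Cd163l1), both named after their values were seen.

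Genes past the threshold were also counted in other splits of the libraries into groups of the same sizes. Splits with as many genes, the real one included, were 2 of 100 in macrophages (real 4, highest other 11) and 1 of 56 in monocytes (234 and 78). They were 3 of 100 in neutrophils (42 and 61) and 2 of 100 in dendritic cells (19 and 21). Because these splits mix the batches while the fit keeps a batch term, they do not exclude chance. The counts in neutrophils and dendritic cells fell to 0 in some fits with 1 library left out. Nor is chance excluded for NK cells (10 and 10, 2 of 34). For B cells (0 and 11, 100 of 100) and T cells (0 and 75, 99 of 99) the splits cannot decide, because with a real count of 0 every split is as large. In B and T cells edgeR called 0 genes, 231 and 286 had an unadjusted p under 0.05 and DESeq2 called 2 in each. The split with 75 T cell genes puts CLP replicate 4 with the 4 libraries of batch B, so with the batch term it sets that library against the others of batch A. With batch B alone the T cell genes past threshold were 12.

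Since those splits mix the batches, grouping by chance within the library batches was counted too, over every split that keeps the group sizes in each batch. The share of splits as large was under 0.05 for macrophages (highest other 96, 4 of 210 splits), monocytes (78, 1 of 24), neutrophils (91, 9 of 210) and dendritic cells (21, 2 of 60). These shares were not adjusted over the classes, so chance is not excluded by them. For B cells (5, 60 of 60) and T cells (3, 60 of 60) the count cannot decide, because with a real count of 0 every split is as large. NK cells have too few such splits for a share under 0.05 (real 10, highest other 7, 1 of 18). Each split as large in the first 4 of these classes left the groups of batch B as they are, and the splits that mixed them gave at most 1 gene there. Among the splits that left them, 4 of 70 were as large in macrophages, 1 of 8 in monocytes, 9 of 70 in neutrophils and 2 of 20 in dendritic cells. The split counts thus depend largely on whether control replicates 5 and 6 are set against CLP replicates 5 and 6. They do not show that the groups of batch A differ as well. Of the macrophage genes, only Slc40a1 and Cfb passed in an edgeR fit of batch A alone (adjusted p = 0.0381 and 0.0490), and neither did in batch B alone (0.104 and 0.255). The highest other counts exceed the real ones in macrophages, neutrophils, dendritic cells, B cells and T cells, several times in macrophages, which points to a structure of the samples whose cause was not tested.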

How the results depend on the processing

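Leaving out CLP replicates 5 and 6, leaving out cluster 10, adding the unnamed clusters, leaving out barcodes rich in haemoglobin, taking monocyte cluster 8 alone, resolution 2.0 for class shares and leaving out libraries in classes other than macrophages were tests chosen only after the result was seen.

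For shares, 178 of the alternative values of the class shares kept their direction and side of the threshold and 2 passed it, both without CLP replicate 3 (adjusted p = 0.0429), where the CLP difference was -2.47 points for class share: conventional dendritic cell (-2.47 to -1.54 over libraries left out) and 13.8 points for class share: neutrophil (8.80 to 13.8). Marker shares stayed on the same side in 35 alternatives, and marker share: Trem2 moved to a difference of -3.47 points unthinned, the cause of which was not tested. All 12 alternatives of the subset shares stayed on the same side. Of the single named genes, 630 alternative values stayed on the same side, 177 no longer passed and 24 newly passed. The macrophage gene Slc40a1 passed in every alternative run except without a batch term (adjusted p = 0.322) and with batch B alone (0.104, or 0.109 without barcodes rich in haemoglobin), with adjusted p from 0.000159 to 0.0338 over libraries left out.

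Macrophage genes higher, 3 as reported, were 71 with DESeq2, 456 with no filter on low counts, 0 with no batch term, 1 with batch A alone, 10 with batch B alone, 6 there without barcodes rich in haemoglobin, 0 without CLP replicates 5 and 6, 0 with the unnamed clusters added, 7 without cluster 10, and 0 to 49 over libraries left out. Macrophage genes lower, 1 as reported, were 53, 186 and 0 in the first 3 of these, 0 with batch B alone with or without those barcodes, 2 without cluster 10, and 1 to 53 over libraries left out. Of the 4 genes called, 4 were among the calls of DESeq2, 1 without CLP replicates 5 and 6 and 0 in batch B alone. A fit on 1 batch has fewer libraries. The cause of the other moves was not tested.

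Monocyte genes past threshold, 234 as reported, were 515 with no filter, 0 with no batch term, 152 with batch B alone, 8 without CLP replicates 5 and 6 (2 of them shared) and 6 to 385 over libraries left out. Neutrophil genes past threshold, 42 as reported, were 67 with DESeq2, 531 with no filter, 5 with no batch term, 26 with the replicate block, 0 with batch A alone, 0 with batch B alone, 0 without CLP replicates 5 and 6 and 0 to 102 over libraries left out. Conventional dendritic cell genes past threshold, 19 as reported, were 233 with no filter, 0 with no batch term, 0 with the replicate block, 0 with batch A alone, 114 with batch B alone, 29 with doublet calls kept, 0 without CLP replicates 5 and 6 and 0 to 40 over libraries left out. The cause was not tested.

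NK cell genes past threshold, 10 as reported, were 50 with no filter, 1 with no batch term, 77 with the replicate block, 5 with batch A alone, 6 with batch B alone, 4 with doublet calls kept, 6 with at least 1000 UMIs per cell, 5 without CLP replicates 5 and 6 and 2 to 20 over libraries left out. B cell genes past threshold, 0 as reported by edgeR (231 at an unadjusted p under 0.05), were 2 with DESeq2, 62 with no filter, 3 with the replicate block, 1 with batch A alone, 52 with batch B alone, 2 without CLP replicates 5 and 6 and 0 to 9 over libraries left out. T cell genes past threshold, 0 as reported by edgeR (286 at an unadjusted p under 0.05), were 2 with DESeq2, 52 with no filter, 3 with the replicate block, 12 with batch B alone and 0 to 7 over libraries left out. The cause was not tested.

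Macrophage gene lists up, 12 as reported, were 0 with an estimated correlation and 2 with fry, and macrophage gene lists down were 1 with batch B alone. With batch B alone, macrophage list cell cycle reversed to a median of -0.21 (adjusted p = 0.00203), against 0.28 in batch A alone (adjusted p = 0.000238), and macrophage list oxidative phosphorylation had a median of 0.0097 with camera giving it as down (adjusted p = 0.927). These are camera values at the preset correlation. With an estimated correlation the cell cycle list did not differ between batches (interaction test, adjusted p = 0.295). The cause of the reversal was not tested. The replicate block assumes pairs the data do not show, since libraries of the same number correlated at -0.07 to -0.0025 after group and batch means were removed and none was best with its own number. Of 2-fold changes put into simulated data, 25% were recovered in monocytes, whose smallest library had 75994 UMIs, and 96.2% in B cells, whose smallest had 26336, so depth alone does not set what can be found. Monocytes of batch A alone had 1 control library and gave no value.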

Other observations

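The tests of glucocorticoid-induced genes were chosen only after the result was seen.

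Dendritic cells and monocytes shared 11 genes called higher (Apobec3, Cebpd, Ifi207, Il4ra, Kdm6b, Ms4a6c, Ms4a6d, Myd88, Orai1, Tle3 and Tmem173), where 17 and 62 calls among 3366 genes tested in both give 0.313 by chance. The cells came from the same libraries, so the classes are not independent. In dendritic cells the CLP difference was greater in batch B for 9 of the 10 genes that differed between batches, among them Socs3 and Mt2, and Tnfaip3 in neutrophils had a log2 fold change of -0.71 in batch A and 3.96 in batch B. These genes were named after their values were seen.

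An unnamed cluster of 249 cells was led by cardiomyocyte genes and made up 1.07% of cells in CLP and 2.28% in control libraries (exact permutation p = 0.0714, two-sided, n = 6 each). Another, of 439 cells, made up 3.82% and 1.39% (exact permutation p = 0.205, n = 6 each), with 12.3% in CLP replicate 4. Among the macrophages of batch B, 4 barcodes held 94.2% to 95.7% haemoglobin UMIs.

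Fkbp5, which glucocorticoids induce, was higher in dendritic cells (log2 fold change 2.75, adjusted p = 0.0107, in 4 of 5 CLP libraries) and in neutrophils (1.86, adjusted p = 0.00903). It did not pass in macrophages, monocytes, NK cells or T cells (adjusted p = 0.205, 0.0995, 0.275 and 0.576). The difference of mean log2 CPM was 2.15 in batch A and 2.91 in batch B in dendritic cells, 0.64 and 2.09 in neutrophils, 0.98 and 4.32 in macrophages, -0.83 and 3.53 in monocytes, 0.01 and 1.29 in NK cells and -0.36 and 1.63 in T cells.

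A candidate explanation of the higher Fkbp5 is a glucocorticoid-type response, which would raise other induced genes (Tsc22d3, Per1, Sgk1, Klf9, Cebpd and Errfi1) as well. In macrophages, dendritic cells and neutrophils, 5 of 12 tests of these genes were higher at an unadjusted p under 0.05 and 0 were lower by edgeR. That set of classes left out monocytes after Sgk1 had been seen to be lower there, so the test was run again over every tested class, where 6 of 21 were higher and 2 lower, both in monocytes (Sgk1 -1.75, Tsc22d3 -1.38). The explanation can be neither excluded nor held on these values.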
